A study of Mus musculus with 6 samples.

How the data were processed

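RNA from purified splenic NK cells of 6 mouse samples, 3 IL-15 transgenic WT and 3 IL-15 transgenic Xbp1s cKO, was extracted with RNeasy columns and made into libraries with the KAPA Hyper Prep kit, per the labels' protocols. Single reads of 50 bp were sequenced on a HiSeq2500, per the labels. The submitters' processing notes name HISAT2, HTSeq and DESeq2, without versions, and the genome build mm10. The alignment and counting settings, the use of strand and the rule by which genes were chosen for the table are not given in the sources used here. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether the 3 libraries of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical.

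The deposited table is called RPKM but its values are CPM, counts per 1000000 reads over the 11717 listed genes. Each of the 6 columns summed to 1000000, and the step between low values was the same for short and long genes, so the authors did not divide by gene length in the deposited values. All values (100%) were whole multiples of the value of 1 read within 0.01 reads, so whole reads were recovered, between 26297292 and 29366756 per library. Because genes were selected before deposit, these totals are reads over the listed genes and not full sequencing depth. The listed gene with the fewest reads had 7 in total over the 6 libraries. The median gene had 911 reads per library, as a mean over the 6 libraries. The largest single share of reads, 4.65% to 6.03% per library, lay on Gm26917, a gene that overlaps a ribosomal RNA repeat, and 0.968% to 1.2% lay on Gm42418, another such gene. Values in CPM compare a gene between libraries, but they do not compare the molar level of short with long genes. A group of transcripts that takes more reads in a library lowers the CPM of all others.

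Gene coordinates were taken from GENCODE M21 on the same build by matching Ensembl identifiers. Of the listed genes, 11709 matched by identifier and 11507 also by version. A spreadsheet had turned 15 symbols into dates, and in all 16 symbols were replaced through their identifiers. Strand use in counting is not stated, so reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies are uncertain.

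The planned design assumed RPKM. Since the values proved to be CPM, the same log-scale test was applied to them. Genes with at least 1 CPM in at least 3 of 6 libraries (11343) were tested on log2(CPM + 0.5) with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance, genotype as the single term and all 6 libraries. Fold changes are on the log2(CPM + 0.5) scale, which understates the change of low genes. P-values were adjusted by Benjamini-Hochberg over all genes tested, at a threshold of 0.05. For Pim2 and Tbx21 the adjustment was also made over the 2 genes alone, and single genes were given a two-sided exact permutation test, which with 3 against 3 libraries cannot go below 0.1. Means are given with the SD over 3 libraries.

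A total of 29 gene lists, chosen before the data were examined from the series title and from textbook knowledge of XBP1s, NK cells and other splenic cells, were tested with camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists with at least 5 tested members. Camera sets the members of a list against all other genes tested. A list called higher or lower is so relative to those genes, and not to a fold change of 0. An estimated correlation and the fry rotation test were run beside it. Members were also adjusted over each list alone. Genes were named by a rule fixed beforehand: Xbp1, Pim2 and Tbx21, the genes past the threshold or, as none passed, the 5 of smallest p in each direction, and the 3 members of smallest p in each list, of which some in lists without a passing member are left out. Cdkn1a, Ccng1, Aen and Cd74 are named in addition and were chosen after their values were seen.

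The recovered reads were tested with the edgeR 4.0.16 quasi-likelihood test and with DESeq2 1.42.0. The planned design held no count test, so both were added after the data were seen. Other alternatives changed the pseudocount (0.1 and 1), the filter (none, or a mean of at least 5 CPM), the scaling (quantile normalization, median ratios), the prior variance, library weights, a block by replicate number, and left out each library in turn. Added after the data were seen were division by exon length, 1 or 2 surrogate variables (sva 3.50.0), removal of the 2 genes on ribosomal RNA repeats, and the edgeR test without WT library 3. The 6 libraries were compared for duplicates, and no pair agreed within sampling noise (chi-square per degree of freedom of at least 4.75).

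The tests were first run on simulated data, 5 sets of reads for the 11343 genes drawn from the real means and depths of cKO against WT, with 200 genes changed in each. Limma recovered 40.6% of the genes changed 1.5-fold, 74.0% of those changed 2-fold and 97.0% of those changed 4-fold, and edgeR 39.7%, 74.3% and 97.0%. DESeq2 recovered 61.2%, 84.8% and 97.3%, and called 208 unchanged genes (0.37%) where limma called 39 (0.07%). These false calls stood beside 205, 284 and 321 changed genes recovered by DESeq2, and 136, 248 and 320 by limma. Far more than 5% of the DESeq2 calls were thus false, and a larger part than in limma. Camera called 5 of 5 simulated lists of 25 genes lowered by 25%, and 1.2% of unchanged lists had a p under 0.05. The lists called lower in the real data had far smaller median changes, from -1.30% to -5.77%. Shifts of that size were not simulated. Real libraries also share variation between genes, which these simulations leave out. Figures were drawn with matplotlib 3.10.9.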

Results

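RNA sequencing was performed on natural killer (NK) cells, innate lymphocytes that kill infected and transformed cells, purified from the spleens of C57BL/6 mice carrying an IL-15 transgene. IL-15 is a cytokine that NK cells need for survival and growth. The 6 libraries formed 2 groups of 3: mice labelled WT and mice labelled as a conditional knockout directed at Xbp1s (cKO). Xbp1s is the spliced form of the transcription factor that drives the unfolded protein response of the endoplasmic reticulum (ER). The table listed 11717 genes. The reads over these genes numbered 27696218, 28585834 and 26297292 in WT libraries 1, 2 and 3, and 29366756, 28471185 and 26907844 in cKO libraries 1, 2 and 3. A single read was worth between 0.0341 and 0.038 CPM (reads of a gene per 1000000 reads over all listed genes), and a gene at 0 reads in a library could have been present at up to 0.102 to 0.114 CPM, counting error only.

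The targeted gene was examined first, as a check of the labels. Xbp1 (ENSMUSG00000020484.19, protein-coding, plus strand of chromosome 11, 5520659 to 5525893, build mm10) was at 42.9, 61.4 and 63.5 CPM in WT libraries 1, 2 and 3 and at 35.1, 33.4 and 39.7 CPM in cKO libraries 1, 2 and 3. The group means were 55.9 ± 11.3 CPM (SD, n = 3) in WT and 36.0 ± 3.25 CPM (SD, n = 3) in cKO. All 3 cKO libraries lay below all 3 WT libraries, and the log2 fold change on the log2(CPM + 0.5) scale was -0.61 (95% confidence interval -0.99 to -0.23). This difference did not pass the limma test over all genes (adjusted p = 1.0), and a two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The values cover the whole gene and do not separate spliced from unspliced transcripts.

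The title of the series names 2 further genes, Pim2 and the gene of T-bet, which set the question of whether their transcripts depend on Xbp1s. Pim2 (ENSMUSG00000031155.16, plus strand of chromosome X, 7878262 to 7883432) encodes a serine/threonine kinase that promotes the survival of lymphocytes. It was at 59.6 ± 7.55 CPM in WT (SD, n = 3) and 45.9 ± 1.28 CPM in cKO (SD, n = 3), and was lower in each cKO library than in any WT library. The log2 fold change was -0.37 (95% confidence interval -0.59 to -0.14), a difference of -22.5%. Pim2 did not pass over all genes (limma, adjusted p = 1.0) and passed when adjusted over Pim2 and Tbx21 alone (limma, adjusted p = 0.0136), while the exact permutation test gave p = 0.1. Tbx21 (ENSMUSG00000001444.2, minus strand of chromosome 11, 97098071 to 97115331), which encodes T-bet, a transcription factor of NK cell maturation, was at 445 ± 75.4 CPM in WT and 411 ± 45.5 CPM in cKO (SD, n = 3 each). Its log2 fold change of -0.11 (95% confidence interval -0.43 to 0.22) was smaller than the spread between libraries (limma, adjusted p = 0.464 over the 2 genes alone, and exact permutation p = 0.7). Without WT library 3, which had the highest Tbx21 level at 524 CPM, the log2 fold change was 0.019.

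**Figure D1:**
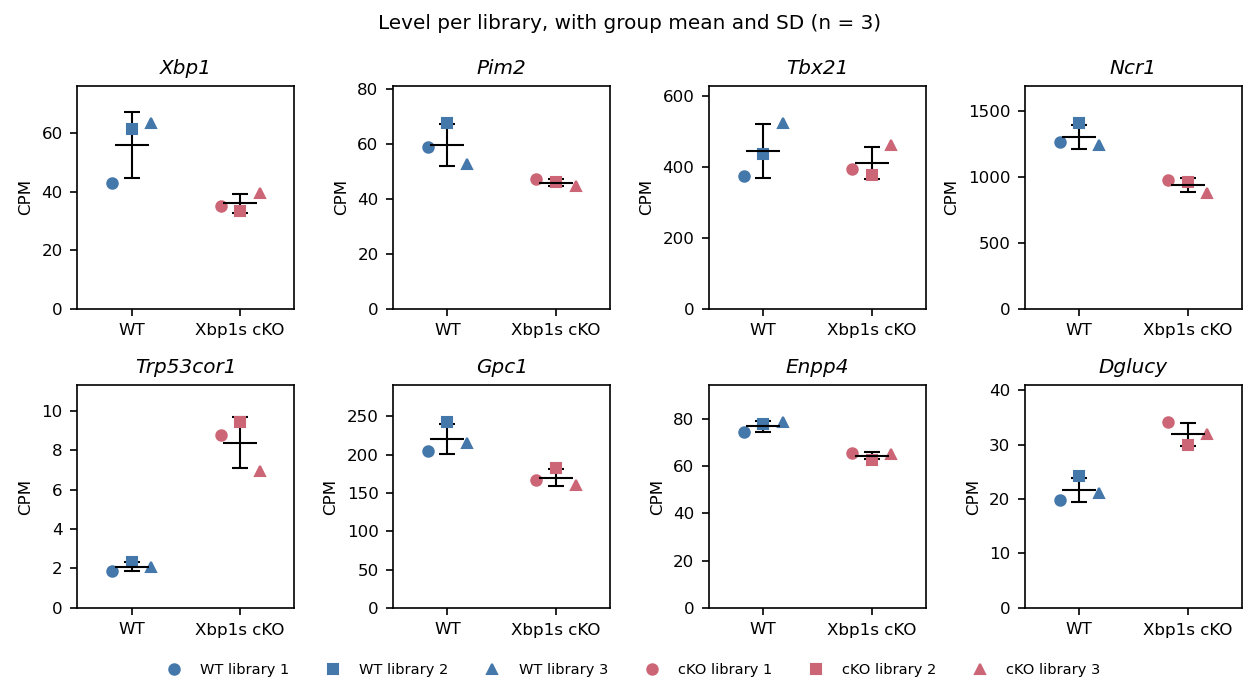
Level of 8 genes in CPM (vertical axes, starting at 0) in the 3 WT and 3 Xbp1s cKO libraries, with points for single libraries, horizontal bars for group means and vertical bars for SD (n = 3). Xbp1, Pim2, Ncr1, Gpc1 and Enpp4 were lower, and Trp53cor1 and Dglucy higher, in all 3 cKO libraries than in all 3 WT libraries, whereas the Tbx21 levels of the 2 groups overlapped.

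Over the whole transcriptome, the gene of smallest p was Trp53cor1 (minus strand of chromosome 17, 29057430 to 29079179), a long noncoding RNA also called lincRNA-p21 that is transcribed from near Cdkn1a and induced by p53. It was at 2.09 ± 0.216 CPM in WT and 8.38 ± 1.28 CPM in cKO (SD, n = 3 each), with a log2 fold change of 1.77. Phlda3, a p53 target that restrains AKT, was at 1.60 ± 0.487 CPM in WT and 3.75 ± 0.205 CPM in cKO, and Dglucy, the mitochondrial D-glutamate cyclase, at 21.7 ± 2.21 and 31.9 ± 2.12 CPM (SD, n = 3 each). Ncr1 (plus strand of chromosome 7, 4337724 to 4345164), which encodes the activating receptor NKp46, was at 1305 ± 90.1 CPM in WT and 940 ± 51.4 CPM in cKO (SD, n = 3 each), a log2 fold change of -0.47. The polyubiquitin gene Ubb was at 387 ± 11.0 and 322 ± 17.9 CPM, and the heparan sulfate proteoglycan gene Gpc1 at 220 ± 19.5 and 170 ± 11.3 CPM (SD, n = 3 each).

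None of the 11343 genes tested passed a false discovery rate of 5% in limma, in either direction, so none of these genes did. The smallest adjusted p was 0.145, for Trp53cor1. At an unadjusted p under 0.05, limma listed 133 genes (96 higher and 37 lower in cKO), which is 1.17% of the genes tested. The edgeR quasi-likelihood test on the recovered reads also called 0 genes and listed 145 at an unadjusted p under 0.05. DESeq2, on the same reads, called 6 genes and listed 155 without adjustment. Its calls were Trp53cor1 (adjusted p = 1.47e-12), Dglucy (adjusted p = 0.0384) and Ighv11-2 (adjusted p = 0.0442), all higher in cKO, and Ncr1 (adjusted p = 2.29e-06), Ubb (adjusted p = 0.0416) and Enpp4 (adjusted p = 0.0416), all lower in cKO. In the simulated data far more than 5% of the DESeq2 calls fell on unchanged genes. The reads of Ighv11-2, an immunoglobulin heavy chain V segment with near-identical relatives, can be split between copies, and its level was low at 0.362 ± 0.0847 CPM in WT and 1.73 ± 0.565 CPM in cKO (SD, n = 3 each). The other genes of smallest p were Atrnl1 (6.14 ± 0.358 CPM in WT and 9.55 ± 0.689 CPM in cKO), Tshz3 (39.3 ± 2.16 and 31.2 ± 1.86 CPM) and Enpp4 (76.8 ± 2.25 and 64.3 ± 1.42 CPM; SD, n = 3 each). The 2 groups did not overlap in 490 genes (4.32% of those tested), where chance alone gives 10%. The median standard error of a log2 fold change was 0.0965.

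The first question about gene groups was whether genes that XBP1s is known to activate, those of ER protein folding, translocation and ER-associated degradation, differed between the genotypes. Of the 68 members tested, 55 were lower and 13 higher in cKO, with a median log2 fold change of -0.042, or -2.87%. The list was called lower by camera with a preset correlation of 0.01 (adjusted p = 8.84e-07 over 29 lists) and was not called with an estimated correlation (adjusted p = 0.47). Sec24d, a subunit of the coat of ER export vesicles, was at 31.3 ± 4.15 CPM in WT and 25.6 ± 0.389 CPM in cKO. Manf, an ER stress-induced secreted factor, was at 49.9 ± 1.69 and 45.7 ± 1.61 CPM, and the ER chaperone gene Hyou1 at 141 ± 5.55 and 130 ± 6.63 CPM (SD, n = 3 each). None of the 68 members passed over all genes or adjusted over the list alone. The call held whichever library was left out, with a median of -0.015 without cKO library 3. The mean of the list over its members was highest in WT libraries 1 and 3, at 0.026 and 0.025 above its mean over all libraries, and lowest in cKO library 3, at -0.042, while cKO library 2 (0.0067) lay above WT library 2 (0.0029). The substrates of IRE1-dependent mRNA decay (median -0.043, 7 of 10 lower, adjusted p = 0.0898) were not called. Nor were the targets of the PERK-ATF4-CHOP branch, another arm of ER stress signalling (14 higher and 14 lower, adjusted p = 0.675). The decay substrates were called lower without cKO library 1 (-0.037, adjusted p = 0.0323) or cKO library 2 (-0.071, adjusted p = 0.0405). For the PERK-ATF4-CHOP targets, the median of 0.00031 and the mean of 0.01 were above 0. The test, which sets a list against the other genes and not against 0, pointed lower.

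The second question was whether survival genes differed. The list of anti-apoptotic and Pim kinase genes was called lower (adjusted p = 0.0283) and was not called with an estimated correlation (adjusted p = 0.819). Of its 18 members 11 were lower and 7 higher, with a median log2 fold change of -0.033. Pim2 had the smallest p, and its values are given above. Bcl2l1, which encodes BCL-XL, was at 75.9 ± 14.8 CPM in WT and 68.0 ± 4.69 CPM in cKO, and Bcl2a1d, of a family of near-identical copies, at 3.13 ± 0.416 and 2.74 ± 0.131 CPM (SD, n = 3 each). The call was absent without WT library 2 (-0.014), WT library 3 (0.015) or cKO library 2 (-0.0058). Without WT library 3 the sign of the median turned while the test still pointed lower, and the log2 fold change of Bcl2l1 turned as well (0.010). The median was -0.066 without WT library 1 and -0.051 without cKO library 3. Pro-apoptotic genes were not called (adjusted p = 0.673), with 11 members higher and 11 lower, and their median of 0.00093 and mean of 0.0096 had the opposite sign to the test. Among them Bax, which permeabilises mitochondria in apoptosis, was at 28.6 ± 1.09 CPM in WT and 31.7 ± 0.202 CPM in cKO (SD, n = 3 each). Genes of the IL-15 receptor, JAK-STAT5 and feedback were not called either (median -0.03, adjusted p = 0.0971), except lower without WT library 1 (-0.086) or cKO library 3 (-0.055). The phosphatase gene Ptpn6 from this list was at 172 ± 27.1 and 208 ± 17.7 CPM.

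The third question concerned NK cell function and maturation. Cytotoxic effector and cytokine genes were called lower (adjusted p = 4.80e-05), with 21 of 25 members lower and a median log2 fold change of -0.085, and were not called with an estimated correlation (adjusted p = 0.665). Nkg7, a protein of cytotoxic granules, was at 855 ± 61.6 CPM in WT and 758 ± 59.4 CPM in cKO, and the cathepsin gene Ctsw at 596 ± 29.1 and 562 ± 14.0 CPM. The granzyme gene Gzmk lay the other way, at 4.44 ± 0.654 CPM in WT and 5.85 ± 0.545 CPM in cKO (SD, n = 3 each). Without WT libraries 1 and 2 in turn the median of this list was -0.14 and -0.055, and without WT library 3 it was -0.016 and the call was absent (adjusted p = 0.352). Mature NK cell and T-bet-associated genes were called lower (median -0.061, 21 of 28 lower, adjusted p = 0.00287) and were not called with an estimated correlation (adjusted p = 0.819). The integrin gene Itgb2 was at 1627 ± 150 and 1426 ± 89.8 CPM, Ly6c2 at 91.5 ± 9.97 and 81.2 ± 10.1 CPM, and Havcr2, which encodes the receptor TIM-3, at 3.89 ± 1.54 CPM in WT and 5.31 ± 1.11 CPM in cKO (SD, n = 3 each). This call was absent without WT library 2 (median -0.011, adjusted p = 0.863) or cKO library 3 (median -0.0058, adjusted p = 0.812). The median was -0.12 without WT library 1 and -0.11 without cKO library 1.

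Genes of immature NK cells were called lower as well (median -0.075, 17 of 26 lower, adjusted p = 0.0283, and adjusted p = 0.819 with an estimated correlation). The chemokine receptor gene Ccr2 was at 504 ± 27.7 CPM in WT and 453 ± 39.0 CPM in cKO, and Thy1 at 143 ± 20.3 and 125 ± 2.12 CPM (SD, n = 3 each). This call was absent without WT library 2 (-0.052), WT library 3 (0.0093) or cKO library 2 (0.058), and the median was -0.13 without WT library 1 and -0.14 without cKO library 3. NK receptors and adaptors were lower in cKO in all 37 members tested, with a median log2 fold change of -0.086, or -5.77% (adjusted p = 2.57e-17, and adjusted p = 0.516 with an estimated correlation). Within this list the inhibitory receptor gene Klra6 was at 15.3 ± 1.71 CPM in WT and 11.9 ± 0.492 CPM in cKO, and Klri2 at 511 ± 23.6 and 451 ± 10.7 CPM (SD, n = 3 each). Adjusted over the list alone, 1 member passed, Ncr1. The call held whichever library was left out, with a median of -0.15 without WT library 1. The mean of the list was lower in WT library 1 (-0.049) than in cKO library 1 (-0.036).

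**Figure D2:**
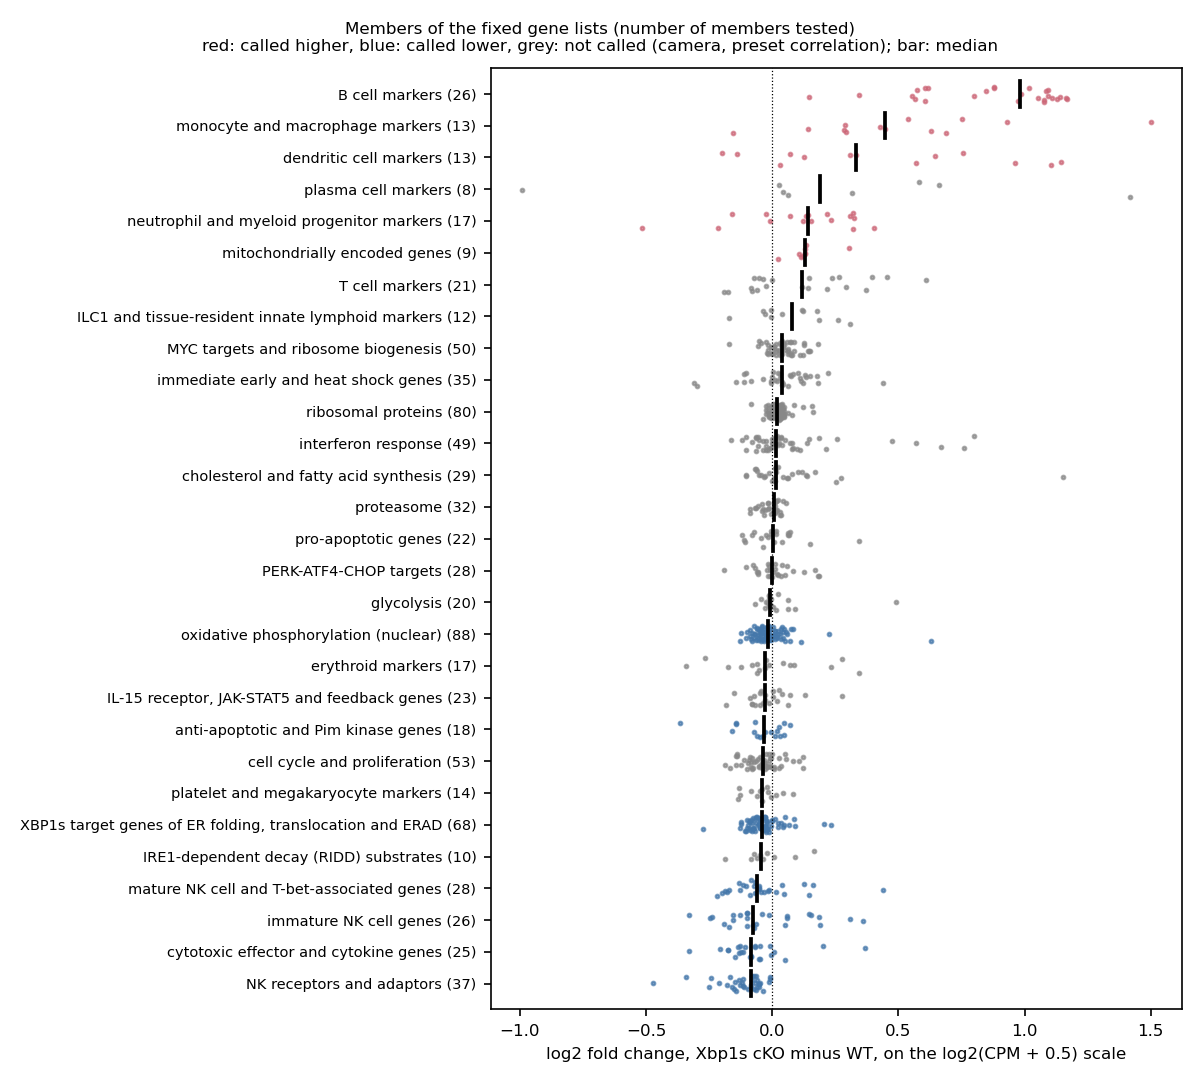
Log2 fold change of each tested member (points; horizontal axis, cKO minus WT on the log2(CPM + 0.5) scale) in the 29 gene lists (vertical axis, with the number of members), with a bar at each median and colour for lists called higher (red), lower (blue) or not called (grey) by camera with a preset correlation. The B cell markers had the highest median, 0.98, and the NK receptors and adaptors the lowest, -0.086.

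Markers of other cells that a splenic preparation can hold were tested too. B cell markers were higher in cKO in all 26 members tested, with a median log2 fold change of 0.98 (adjusted p = 4.55e-15, and adjusted p = 0.665 with an estimated correlation), although 0 of the 26 had an unadjusted p under 0.05 in limma and in 0 did all cKO libraries lie on one side of all WT libraries. The MHC class II gene H2-Eb1 was at 85.4 ± 6.11 CPM in WT and 130 ± 42.5 CPM in cKO, H2-Ab1 at 95.5 ± 7.07 and 153 ± 55.9 CPM, and the light chain gene Iglc2 at 13.2 ± 6.12 and 23.8 ± 8.39 CPM (SD, n = 3 each). Of the 26 markers, 22 were lowest in WT library 3, and 22 were lower in cKO library 2 than in WT libraries 1 and 2. Without WT library 3 the median was 0.32, still called (adjusted p = 3.50e-04), and without cKO library 2 it was 1.47. Monocyte and macrophage markers were called higher (median 0.45, 12 of 13 higher, adjusted p = 1.57e-06, and adjusted p = 0.665 with an estimated correlation). Axl, a receptor kinase of macrophages, was at 4.97 ± 1.87 and 15.7 ± 8.58 CPM, Mpeg1 at 74.8 ± 10.01 and 102 ± 22.5 CPM, and Adgre1, which encodes F4/80, at 2.05 ± 0.625 and 4.74 ± 2.85 CPM (SD, n = 3 each). The median of this list was 0.17 without cKO library 1, 0.26 without WT library 3 and 0.68 without cKO library 3, and it was called each time.

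Dendritic cell markers (median 0.33, 11 of 13 higher, adjusted p = 0.00347, and adjusted p = 0.516 with an estimated correlation) and markers of neutrophils and their progenitors (median 0.14, 12 of 17 higher, adjusted p = 0.0332, and adjusted p = 0.691 with an estimated correlation) were also called higher. Cd209a, a lectin of dendritic cells, was at 2.37 ± 1.12 CPM in WT and 5.80 ± 3.16 CPM in cKO. The granule genes Ngp and Camp were at 29.3 ± 3.04 and 6.53 ± 0.0182 CPM in WT and at 36.4 ± 4.50 and 8.33 ± 1.15 CPM in cKO (SD, n = 3 each). The dendritic call was absent without cKO library 3 (0.17, adjusted p = 0.0981), and its median was 0.22 and 0.16 without WT libraries 1 and 2 in turn. The neutrophil call was absent without WT library 1 (0.25, adjusted p = 0.0563), WT library 3 (0.11, adjusted p = 0.587), cKO library 1 (0.13, adjusted p = 0.617) or cKO library 2 (0.14, adjusted p = 0.12), and its median was 0.24 without cKO library 3. Plasma cell markers (median 0.19, adjusted p = 0.0971), markers of ILC1 and tissue-resident innate lymphoid cells (0.077, adjusted p = 0.448), platelets (-0.04, adjusted p = 0.347) and erythroid cells (-0.028, adjusted p = 0.61) were not called. Without single libraries, plasma cell markers were called higher without WT library 1 (0.54) or cKO library 1 (0.37), ILC1 markers higher without cKO library 2 (0.11), platelet markers lower without WT library 1 (-0.13) or WT library 2 (-0.26) and higher without WT library 3 (0.29), and erythroid markers higher without WT library 1 (0.50) and lower without WT library 2 (-0.29) or cKO library 2 (-0.41). T cell markers were not called (adjusted p = 0.978), with a median of 0.12 and a mean of 0.12 above 0 against a test that pointed lower, and were called higher without WT library 2 (0.23) and lower without WT library 3 (-0.14) or cKO library 1 (-0.081).

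**Figure D3:**
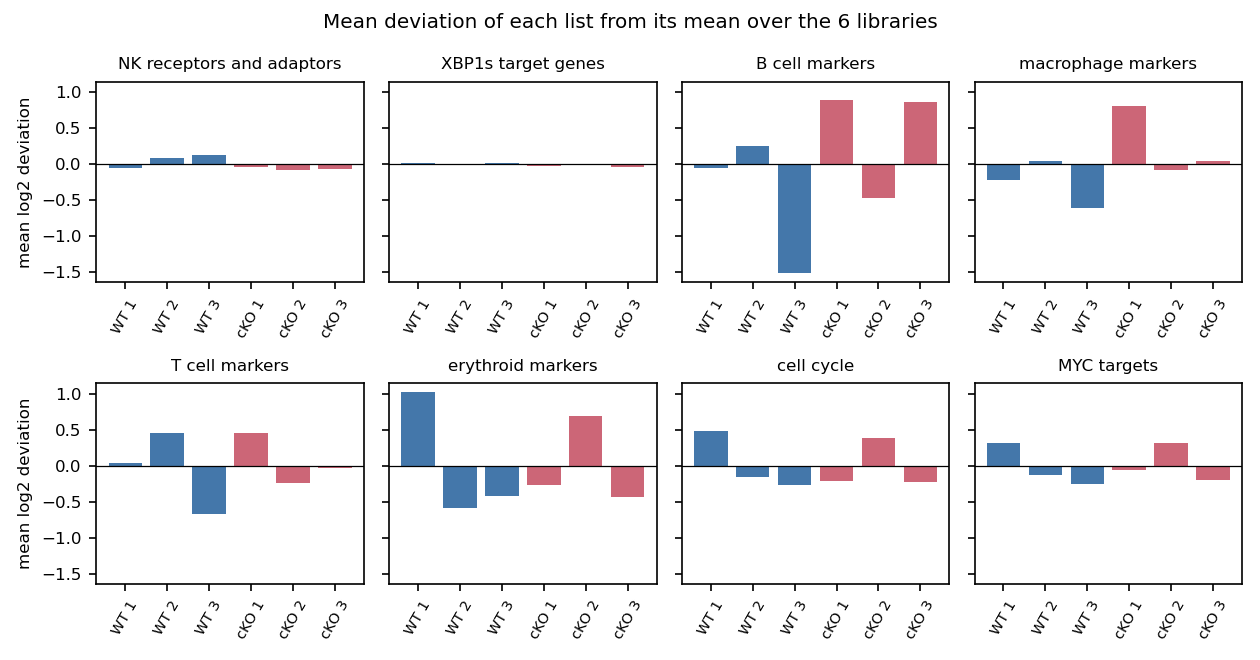
Mean log2 deviation of the members of 8 gene lists from their mean over the 6 libraries (vertical axes), with 1 bar for each WT (blue) and Xbp1s cKO (red) library. The B cell markers stood lowest in WT library 3 (-1.51), and the erythroid, cell cycle and MYC target lists were highest in WT library 1 and cKO library 2.

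Metabolic and growth programmes made up the remaining lists. All 9 mitochondrially encoded genes tested were higher in cKO, with a median log2 fold change of 0.13 (adjusted p = 4.64e-04, and adjusted p = 0.665 with an estimated correlation). The complex I subunit genes mt-Nd4 and mt-Nd5 were at 354 ± 26.1 and 427 ± 48.8 CPM in WT and at 387 ± 19.0 and 466 ± 14.8 CPM in cKO (SD, n = 3 each). This call was absent without WT library 3 (median 0.048, adjusted p = 0.186), and the median was 0.21 without WT library 1. Nuclear genes of oxidative phosphorylation were called lower by a small margin (median -0.019, 59 of 88 lower, adjusted p = 0.0349, and adjusted p = 0.992 with an estimated correlation). Their call was absent without cKO library 1 (-0.016, adjusted p = 0.0774), and without WT library 1 (0.054, adjusted p = 0.0373) or cKO library 3 (0.059, adjusted p = 6.43e-04) they were called higher instead. Their median was -0.035, -0.085 and -0.10 without WT library 2, WT library 3 and cKO library 2 in turn.

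Glycolysis genes were not called (adjusted p = 0.978), and their median of -0.0082 and mean of 0.024 differed in sign. The hexokinase gene Hk2 was at 7.30 ± 1.36 CPM in WT and 10.3 ± 0.223 CPM in cKO (SD, n = 3 each). Proteasome genes were not called either (adjusted p = 0.16), with a median of 0.0054 above 0 and a mean of -0.009 below it, and were called lower without WT library 2 (-0.027), WT library 3 (-0.053) or cKO library 2 (-0.080) and higher without cKO library 3 (0.057). Cell cycle genes (median -0.037, adjusted p = 0.0967), MYC targets (0.039, adjusted p = 0.635), ribosomal proteins (0.018, adjusted p = 0.635), cholesterol and fatty acid synthesis (0.014, adjusted p = 0.448), interferon response genes (0.016, adjusted p = 0.768) and immediate early and heat shock genes (0.038, adjusted p = 0.978) were not called. Several of these lists were called when a single library was left out. Cell cycle genes were called higher without WT library 1 (0.20) and lower without WT library 2 (-0.12), WT library 3 (-0.19) or cKO library 2 (-0.24). MYC targets and ribosomal proteins were called higher without WT library 1 (0.20 and 0.080) or cKO library 3 (0.15 and 0.099) and lower without WT library 3 (-0.070 and -0.037) or cKO library 2 (-0.11 and -0.058). Immediate early and heat shock genes were called lower without WT library 1 (-0.089) or cKO library 3 (-0.11) and higher without WT library 3 (0.16) or cKO library 2 (0.15). Interferon response genes were called higher without WT library 2 (0.035) or cKO library 3 (0.058), and cholesterol and fatty acid synthesis higher without cKO library 3 (0.044). The interferon-induced GTPase gene Mx2 was at 1.66 ± 0.322 and 3.33 ± 1.01 CPM, and the stress-induced gene Sesn2 from the PERK-ATF4-CHOP list at 18.5 ± 0.697 and 21.1 ± 1.18 CPM (SD, n = 3 each). In all, 12 of the 29 lists were called with the preset correlation, 5 higher and 7 lower, and 0 with an estimated correlation. The list means per library of the 2 groups overlapped in all 29 lists, the 12 called ones included.

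The libraries did not group by genotype. WT library 1 was closest to cKO library 2 (Pearson correlation over genes of 0.996), and WT library 2 to cKO library 1 (0.996), while WT libraries 1 and 3 were the least alike of the 15 pairs (0.979). Genes are not independent replicates, so these correlations describe the libraries only. The first principal component held 46.2% of the variance and placed WT library 1 (-22.2) and cKO library 2 (-18.8) apart from the other 4 libraries (4.35 to 16.7). The second held 30.8% and set WT library 3 (23.0) apart from cKO library 1 (-16.3).

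**Figure D4:**
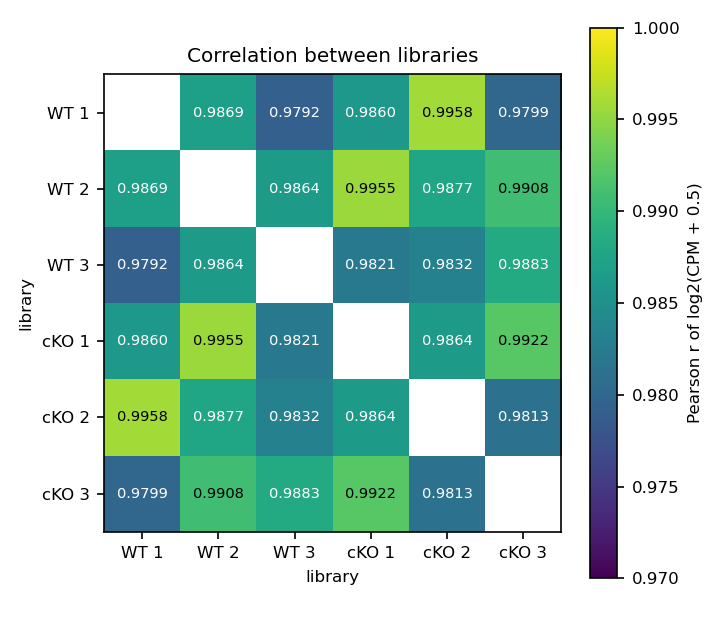
Pearson correlation of log2(CPM + 0.5) over the 11343 genes tested between each pair of the 6 libraries (both axes), coloured and printed per pair. The highest values, 0.9958 and 0.9955, join a WT with a cKO library.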

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

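The tests under edgeR and DESeq2, exon length, surrogate variables and the 2 genes on ribosomal RNA repeats were chosen after the data were seen. So was edgeR without WT library 3, and the other alternatives were chosen before. Xbp1 was lower in cKO under all 23 alternatives run for it, with log2 fold changes from -0.79 to -0.51, and Pim2 under all 23, from -0.48 to -0.27. The lists of XBP1s targets, NK receptors and B cell markers each had the same call in 20 of 22 alternatives. Those 20 all kept the preset correlation of 0.01, and the 2 that did not, the estimated correlation and fry, gave no call. The estimated correlations of the 3 lists were 0.0298, 0.282 and 0.868, so the calls rest on the preset. The count of 0 genes past the threshold was the same under 21 of 23 alternatives. A planned rescaling of each library to a sum of 1000000 left the values as they were, because they already had that sum, and was not run. The few reads of low genes and the 3 libraries per group both limit the tests. The median gene had 911 reads per library. Libraries of the same genotype differed by more than sampling noise, with a chi-square per degree of freedom of at least 16.84. Over all genes together the spread between libraries thus exceeded counting error. Which of them limits more for low genes alone was not tested. The cause of the changes below was not tested.

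The library numbers did not pair the samples. The deviations of same-numbered libraries from their group means correlated at -0.169, -0.506 and 0.482 over genes, and not every library correlated best with its own number. With the replicate block, limma called 0 genes (118 at an unadjusted p under 0.05), 5 lists were higher and 7 lower.

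DESeq2 called 6 genes, 3 higher and 3 lower. Array weights also gave 6, 3 higher and 3 lower (2083 at an unadjusted p under 0.05, against 415 and 557 with 1 and 2 surrogate variables, which called 0), among them Xbp1 at -0.76 (limma, adjusted p = 0.046, where its adjusted p over the alternatives lay between 0.046 and 1.0). Tbx21 was at 0.0058 in edgeR without WT library 3, where 0 genes were called. With an estimated correlation, and in the fry rotation test, 0 lists were called higher and 0 lower, so the XBP1s targets (-0.042), anti-apoptotic genes (-0.033), effector genes (-0.085) and mature NK cell genes (-0.061) had the same medians and no call. The smallest adjusted p were 0.47 and 0.965 (limma). With quantile normalization 3 lists were called lower, the anti-apoptotic (-0.060) and mature NK cell genes (-0.049) were not, and medians turned for pro-apoptotic genes -0.019, PERK-ATF4-CHOP targets -0.017, cholesterol synthesis -0.0028, proteasome -0.003 and T cell markers -0.054. The median of all genes then moved from 0.0087 to -0.0082. The calls of immature NK cell genes, oxidative phosphorylation and neutrophil markers also ended with quantile normalization, and ribosomal proteins were then called higher. The anti-apoptotic genes were not called either with a mean of at least 5 CPM (-0.033), array weights (-0.016) or 2 surrogate variables (-0.023). Further calls that ended were oxidative phosphorylation (median ratios, a mean of at least 5 CPM, array weights), immature NK cell genes (median ratios), dendritic markers (a mean of at least 5 CPM) and neutrophil markers (2 surrogate variables, without the genes on ribosomal RNA repeats). Some lists kept a call with a median that moved by over 1.5 times: with 2 surrogate variables B cell markers fell to 0.14, monocyte markers to 0.12, mitochondrial genes to 0.072 and effector genes to -0.049, with array weights monocyte and neutrophil markers rose to 0.78 and 0.23, and without the genes on ribosomal RNA repeats oxidative phosphorylation stood at -0.012. Lists newly called were plasma cell markers (higher, array weights and exon length), cell cycle genes (lower, array weights and 1 surrogate variable), MYC targets (higher, 1 and 2 surrogate variables) and, with 2 surrogate variables, immediate early and platelet lists higher and T cell markers lower. Medians also turned with median-ratio scaling (pro-apoptotic genes -0.012, PERK-ATF4-CHOP targets -0.012 and proteasome -0.0075), a mean of at least 5 CPM (PERK-ATF4-CHOP targets -0.0015 and T cell markers -0.025), array weights (pro-apoptotic genes -0.0078 and erythroid markers 0.16), exon length (PERK-ATF4-CHOP targets -0.0015 and T cell markers -0.014) and 2 surrogate variables (IL-15 and JAK-STAT5 genes 0.014, cell cycle genes 0.012, T cell markers -0.18, erythroid markers 0.11 and platelet markers 0.30).

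Without single libraries the number of lists called was 5 to 10 higher and 7 to 11 lower, with 0 genes called each time (58 to 391 at an unadjusted p under 0.05). Depending on the library left out, 9 lists were called in both directions: oxidative phosphorylation and 8 that were not called with all 6 libraries. The log2 fold change of Tbx21 was -0.22 (WT 1) to 0.019 (WT 3), and that of Bcl2l1 -0.24 (WT 1) to 0.010 (WT 3), where the brackets name the library left out. Some other named genes kept their sign but also moved. Thy1 ranged from -0.275 to -0.08, Ly6c2 from -0.263 to -0.0846 and Ptpn6 from 0.14 to 0.359. Iglc2 ranged from 0.458 to 1.19 and Adgre1 from 0.516 to 1.25. The list medians ranged as follows: anti-apoptotic genes -0.066 (WT 1) to 0.015 (WT 3), effector genes -0.14 (WT 1) to -0.016 (WT 3), mature NK cell genes -0.12 (WT 1) to -0.0058 (cKO 3), immature NK cell genes -0.14 (cKO 3) to 0.058 (cKO 2), pro-apoptotic genes -0.036 (cKO 2) to 0.011 (cKO 3), IL-15 and JAK-STAT5 genes -0.086 (WT 1) to 0.019 (WT 3), PERK-ATF4-CHOP targets -0.059 (cKO 2) to 0.081 (WT 1), MYC targets -0.11 (cKO 2) to 0.20 (WT 1), ribosomal proteins -0.058 (cKO 2) to 0.099 (cKO 3) and glycolysis -0.031 (cKO 2) to 0.067 (cKO 3). Medians of further lists that turned sign were oxidative phosphorylation -0.10 (cKO 2) to 0.059 (cKO 3), cell cycle genes -0.24 (cKO 2) to 0.20 (WT 1), interferon response -0.015 (WT 1) to 0.058 (cKO 3), cholesterol synthesis -0.018 (cKO 2) to 0.044 (cKO 3), proteasome -0.080 (cKO 2) to 0.057 (WT 1), immediate early genes -0.11 (cKO 3) to 0.16 (WT 3), T cell markers -0.14 (WT 3) to 0.23 (WT 2), erythroid markers -0.41 (cKO 2) to 0.50 (WT 1), platelet markers -0.26 (WT 2) to 0.29 (WT 3) and ILC1 markers -0.013 (cKO 3) to 0.12 (WT 3).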

Other observations

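The tests in this part were all chosen after the results they bear on had been seen. Programmes of dividing cells separated libraries across the genotypes. Cell cycle and proliferation genes lay 0.49 and 0.38 (mean log2 deviation from the mean over the 6 libraries) higher in WT library 1 and cKO library 2, and between -0.27 and -0.16 in the other 4 libraries. MYC targets, at 0.33 and 0.32, and erythroid markers, at 1.03 and 0.69, were also highest in those 2 libraries. Immediate early and heat shock genes, which respond to handling of cells, were highest in WT library 3 and cKO library 3, at 0.35 and 0.34.

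Several targets of p53 besides Trp53cor1 and Phlda3 were higher in all 3 cKO libraries than in all 3 WT libraries. The cell cycle inhibitor gene Cdkn1a was at 6.41 ± 1.21 CPM in WT and 9.98 ± 0.451 CPM in cKO, Ccng1 at 101 ± 4.87 and 113 ± 2.28 CPM, and the exonuclease gene Aen at 26.7 ± 1.56 and 32.5 ± 3.39 CPM (SD, n = 3 each). None of these passed over all genes. Bax and Sesn2, also p53 targets, had been named from other lists for their small p.

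The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. For genes past the threshold the real split gave 0 and the highest other 1, so all 10 splits gave a count as large. At an unadjusted p under 0.05 the real split gave 133 genes and the highest other 2495, and 8 splits gave as many as the real one. For gene lists called, the real split gave 12 and the highest other 18, and 8 splits gave as many. The count of 2495, several times the real one, points to a structure of the samples other than genotype. The absolute median of the XBP1s targets was 0.042 in the real split and 0.052 in the highest other, that of the NK receptors 0.086 and 0.11, and that of the B cell markers 0.981 and 1.504.

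B cell markers were called higher and NK receptors lower in cKO with the preset correlation and not with an estimated one (adjusted p = 0.665 and 0.516), and the list means of the 2 groups overlapped in both. The B cell markers moved together over the 6 libraries (median pairwise Pearson correlation 0.981, median Spearman correlation 0.943, and Pearson 0.954 without WT library 3 and cKO library 1), which is consistent with RNA of B cells in the preparations. Whether such RNA also accounts for the lower NK receptors cannot be told apart from other sources, because within the groups the B cell and NK receptor means per library correlated at -0.334 with a 95% interval of -0.939 to 0.777 over the 6 libraries. The NK receptors were lowest in cKO library 2 (-0.074), where the B cell markers were low (-0.46), and raised in WT library 2 (0.091), where the B cell markers were raised (0.26). Going the other way, WT library 3 had the highest receptors (0.135) and the lowest B cell markers (-1.51). The receptors were also low in cKO libraries 1 and 3 (-0.036 and -0.067), where the B cell markers were high (0.893 and 0.874). In WT library 1 both lay below 0 (-0.049 and -0.052). Over all 6 libraries, with the genotype difference left in, the 2 means correlated at -0.574. The B cell list includes MHC class II genes that other antigen-presenting cells express, its abundant member Cd74 was at 325 ± 45.2 CPM in WT and 525 ± 198 CPM in cKO (SD, n = 3 each), and the labels call the cells purified without naming a sort or gate. A lower share of NK cells beside all other cell types cannot be told apart from this, since the B cell index minus the mean of the T cell, erythroid and platelet indices was 0.846 higher in cKO (log2) with overlapping groups. If the receptors' median of -0.086 measures dilution of NK cell RNA, dilution would lower NK transcripts by about that much. The upper 95% bounds, unadjusted for the number of genes, of Xbp1 (-0.232) and Pim2 (-0.14) lay below that median. On that condition they argue against dilution as the whole cause for these 2 genes, while the bound of Tbx21 (0.219) leaves it open. The median was used without an interval, and the single receptors ranged from -0.473 to -0.0103. Ncr1 was the lowest of the 37 receptors and Klra6 the next, with 95% intervals that overlap (-0.655 to -0.291 and -0.599 to -0.087). A recombinase allele at Ncr1 could lower its transcript, which was not tested because the labels name no driver.

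The higher p53 targets were weighed next. On a list written after Trp53cor1, Phlda3, Cdkn1a, Ccng1 and Aen were seen, the 32 other targets, without Bax and Sesn2, had a median log2 fold change of 0.063, with 23 higher and 9 lower, and 0.04% of 10000 random lists matched on expression had a median as high, which may reflect a wider rise of p53 target transcripts in cKO. Random lists ignore that genes move together, and among the 10 splits the highest other absolute median was 0.048. RNA of B cells in amounts that follow their markers is argued against as the cause for Trp53cor1. With the mean of the B cell markers per library in the model, Trp53cor1 stood at 1.82 (95% confidence interval 1.35 to 2.30). The median of those markers then fell from 0.98 to -0.018. A fall to near 0 was fixed by the model, whose mean was taken from the same markers, and is no separate check. Beside the plasma cell markers the lower 95% bound of Trp53cor1 was 1.42, and beside Ighg1, whose own log2 fold change was 1.42, it was 1.214. The median of the B cell markers stayed at 0.8528 and 0.5575 in these 2 models. Both thus left much of the B cell difference in place and cannot decide on B cell RNA itself. Trp53cor1 was highest in cKO library 2, at 9.41 CPM, where the B cell markers lay below those of WT libraries 1 and 2. RNA of monocytes, macrophages or dendritic cells, whose markers were also called higher in cKO, was not put in the model. Whether the loss of Xbp1s, the recombinase or another difference between the mice underlies the higher Trp53cor1 was not tested.

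WT library 1 and cKO library 2, and WT library 2 and cKO library 1, were closest to each other. An exchange of labels needs both libraries out of place. In 0 of the 9 exchanges of a WT with a cKO library did both Xbp1 levels lie beyond the midpoint of the group means (46.0 CPM), and cKO libraries 2 and 1 were the lowest of the 6. This count was fixed by the groups not overlapping in Xbp1, so it adds no separate test of an exchange. Xbp1 over the whole gene need not fall if only part of it is deleted, and the labels do not name the part. WT library 1 alone lay beyond the midpoint at 42.9 CPM, above the highest cKO library (39.7 CPM), so a wrong label on WT library 1 alone cannot be told apart, and it would not account for the other pair. Trp53cor1 (1.88 CPM), Ncr1 (1264 CPM) and Dglucy (19.9 CPM) of WT library 1 lay with WT, as its label says, but these genes were named for parting the groups. Trp53cor1 was also the gene of smallest p without WT library 1. Of the 50 genes of smallest p without WT library 1, 39 put it nearer to cKO, and of the 50 without cKO library 2, 44 put that nearer to WT. For WT library 3, 37 of 50 also put it nearer to cKO, so the count for WT library 1 is not particular to it. The count nearer to cKO was 24 for WT library 2, and the counts nearer to WT were 20 and 23 for cKO libraries 1 and 3. A shared collection or library batch cannot be told apart from other sources, because the labels give none, while the deviations from the group means correlated at 0.586 over genes for WT library 1 with cKO library 2, at 0.647 for WT library 2 with cKO library 1 and at 0.482 for WT library 3 with cKO library 3. The 3 deviations of a group sum to 0, so these values are not independent. No biological explanation was tested for this pattern.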
